A study of Mus musculus with 16 samples.

How the data were processed

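Total RNA of microglia sorted by flow cytometry was measured in 16 mouse libraries, 3 per genotype at P9 and at P14 and 2 per genotype in adults of 3 months. Per the labels' protocols, microglia were isolated without enzymes from each brain and sorted into TRIzol. Complementary DNA was made with SMART-Seq v4 and 15 cycles of amplification, and 1 ng of it went into Nextera XT libraries, a protocol that keeps no strand information. Per the submitters' processing notes, reads were handled with bcl2fastq, STAR 2.5.2b, Picard 2.17.11 and Subread featureCounts on mm10, with no versions given for bcl2fastq and featureCounts. The deposited values are read counts per gene, 1 table per library, in the layout of STAR's own gene counts rather than that of featureCounts. Each table holds 55536 genes after 4 entries that name no gene, and all 55536 identifiers occur in GENCODE mouse release 21, which supplied symbols and exon coordinates. The unstranded counts were used, because the 2 strand-specific columns were near equal in every library (ratio 0.995 to 1.00).

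Reads assigned to genes had a median of 12.96 M per library (9.98 M to 14.8 M) out of 15.1 M to 19.9 M. Per library they were, in M reads, 13.1, 12.8 and 13.3 (WT P9), 14.8, 14.6 and 13.6 (IRF8KO P9), 14.1, 14.6 and 13.6 (WT P14), 10.8, 11.7 and 10.4 (IRF8KO P14), 11.4 and 9.98 (WT adult) and 10.1 and 10.0 (IRF8KO adult). Between 21.9% and 47.0% of reads (median 28.8%) named no gene, and 6.41% to 9.05% of uniquely mapped reads were ambiguous between genes. The share of uniquely mapped reads outside genes was 13.7%, 9.99%, 9.71%, 22.4%, 25.0% and 29.4% on average in WT P9, IRF8KO P9, WT P14, IRF8KO P14, WT adult and IRF8KO adult libraries. Mitochondrial genes held 0.111% to 0.594% of gene reads, and 17350 to 26181 genes had at least 1 read. Correlations of log2 CPM ran from 0.861 to 0.976 within groups (median 0.962) and from 0.751 to 0.953 between groups (median 0.886). Library 3 of the IRF8KO P14 group lay farthest from its group (0.861 and 0.890). The variance between replicate counts was 9.74 to 134.7 times that of counting error alone, so intervals and floors based on counting cover only that error. All libraries read Xist, and 4 Y-linked genes had 0 to 6 reads in total per library, as female labels require.

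Comparisons used edgeR 4.0.16 and limma 3.58.1 under R 4.3.3. Libraries were scaled by TMM, and 18295 genes passed filterByExpr. A quasi-likelihood negative binomial fit with a factor of 6 groups (residual degrees of freedom 10, median prior 7.41) was tested for IRF8KO against WT at each age and averaged over the 3 ages. It was also tested for the change of that effect from P9 to P14 and from P14 to adults, and for each genotype between consecutive ages. P-values were adjusted by Benjamini-Hochberg within each comparison, with calls at 0.05. Standard errors of log2 fold changes come from the fold change and its F statistic. CPM were computed here from TMM-scaled library sizes, and log2 CPM for correlations, components and list means used a prior count of 2. Where a group had 0 reads, the fold is a lower bound with 3 reads placed over that group. Where it had 1 to 3 reads, the ratio is given with an exact 95% counting interval in place of the fitted value.

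A total of 25 gene lists were written from textbook knowledge before the data were examined, 13 of function, 2 technical and 10 of cell types. Those of function are the homeostatic microglia signature, disease-associated microglia, interferon-stimulated genes, MHC class I, MHC class II, phagocytic and Fc receptors, lysosome, cell cycle, inflammatory cytokines and sensors, macrophage transcription factors, TGF-beta signalling, cholesterol synthesis, and LXR targets with lipid handling. The technical ones are dissociation with immediate early genes and mitochondrially encoded genes. The cell types are border-associated macrophages, monocytes, neutrophils, dendritic cells, lymphocytes, neurons, astrocytes, oligodendrocyte lineage, endothelial with mural cells, and erythroid cells. Lists with at least 5 tested members were tested by camera with an inter-gene correlation of 0.01, adjusted over 25 lists and 3 ages together for genotype and within the comparison otherwise. The test was repeated with a correlation estimated per list and with fry. Calls inside a list were also adjusted over the list alone. A set of genes next to Irf8 and a set of sex-linked genes served as checks of the labels.

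Genes are named by a rule fixed before the data were examined. Irf8 comes first, then for each genotype comparison the 10 largest fold changes each way among genes with an adjusted p below 0.05, no overlap between groups, a mean of at least 10 CPM in the higher group and no predicted-model symbol. To these are added up to 4 members per list with the smallest adjusted p, or the 2 most abundant members, and 6 genes each way for comparisons between ages and for interactions. From these the text takes a selection by known function, and well-known members of a list are given whether or not they passed. Because counting ignored strand, genes that share exon bases with another gene are uncertain. Among genes named with a value, at least 10% is shared by Gins2 (67.3% of exon bases shared), Tgm2 (21.8%), Adora3 (20.9%), Spp1 (18.8%), Csf1r (15.1%), Rtp4 (13.9%) and H2-DMa (10.4%). Smaller shares are found in Hs3st2 (9.1%), Meg3 (8.3%), Itga4 (8.0%), Jun (7.3%), Npc1 (5.3%), Apoc4 (4.7%), Tap1 (3.9%) and others below these. Irf8, Spint1, Sall1, Pf4, Clec12a, Apoe, Axl and Ctsh share 0%. Members of close gene families, such as H2-Q6, H2-Q7, Hspa1b and Naip6, are uncertain too and are not reported one by one.

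The procedure was tested on simulated data drawn with each gene's measured mean and spread, in which 100 genes per comparison were changed 2-fold and 100 were changed 8-fold. Of the changed genes with a 2-fold change, 1 of 96, 4 of 93 and 1 of 92 tested were recovered at P9, P14 and in adults. With an 8-fold change 63 of 94, 65 of 96 and 58 of 93 were. False calls numbered 2 of 66, 0 of 69 and 2 of 61. Few genes were changed in this simulation, so its threshold was stricter than in the real comparisons, which have more calls, and the share of 2-fold changes recovered there was not measured. A gene not called is not shown to be unchanged.

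Alternatives set before the data were examined were DESeq2 1.42.0, voom with quality weights, RLE and upper quartile factors, no filter, a filter of 5 CPM in 2 libraries, a fit of only the groups compared, a block on replicate number, a threshold of 1 on the absolute log2 fold change, and leaving out each library. Upper quartile factors shift all P9 log2 fold changes by a median of -0.128. Chosen after results were seen were the share of reads outside genes as a covariate, the same alternatives for genes shared by the 3 ages, and leaving out the most distant library in comparisons that do not contain it. For chance, all 10 splits of 6 libraries were refitted for comparisons of 3 against 3, and 100 regroupings were drawn for the averaged effect and for the P14 minus P9 interaction. With 2 libraries per genotype the adult comparison has too few splits to be tested this way and none were run. Genotype and age were taken from the labels. Exon-level reads, the construct of the targeted allele and the raw reads were not used here.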

Results

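Microglia, the resident macrophages of the brain, were sorted by flow cytometry from wild-type (WT) mice and from mice labelled IRF8KO at postnatal day 9 (P9), postnatal day 14 (P14) and 3 months (adult). IRF8 is a transcription factor of the interferon regulatory factor family that several myeloid lineages need for their development. The 16 libraries, all labelled female, comprise 3 per genotype at P9, 3 per genotype at P14 and 2 per genotype in adults. Reads assigned to genes ran from 9.98 M to 14.8 M per library, with a median of 12.96 M. The labels say that microglia were isolated from each brain but nothing more about animals or litters, so the p-values below measure the spread between these samples. Adult titles of both genotypes carry batch number 2, so adult age and batch cannot be told apart in comparisons between ages.

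A principal component analysis separated the genotypes on its second component. The first component carried 48.4% of the variance and the second 16.9%. On the second component all 8 WT libraries had positive scores (40.5 to 87.7) and all 8 libraries labelled IRF8KO had negative ones (-92.9 to -15.2). On the first component the libraries labelled IRF8KO at P14 (58.3 to 133.8) lay beside the adults of both genotypes (101.0 to 151.8), while the WT P14 libraries (-124.2 to -93.7) lay beside the libraries labelled IRF8KO at P9 (-137.6 to -93.2) and the WT P9 libraries (-36.4 to -15.0) between. This is not an order of age, and the group means on it rank as those of the neuron list described below.

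**Figure D1:**
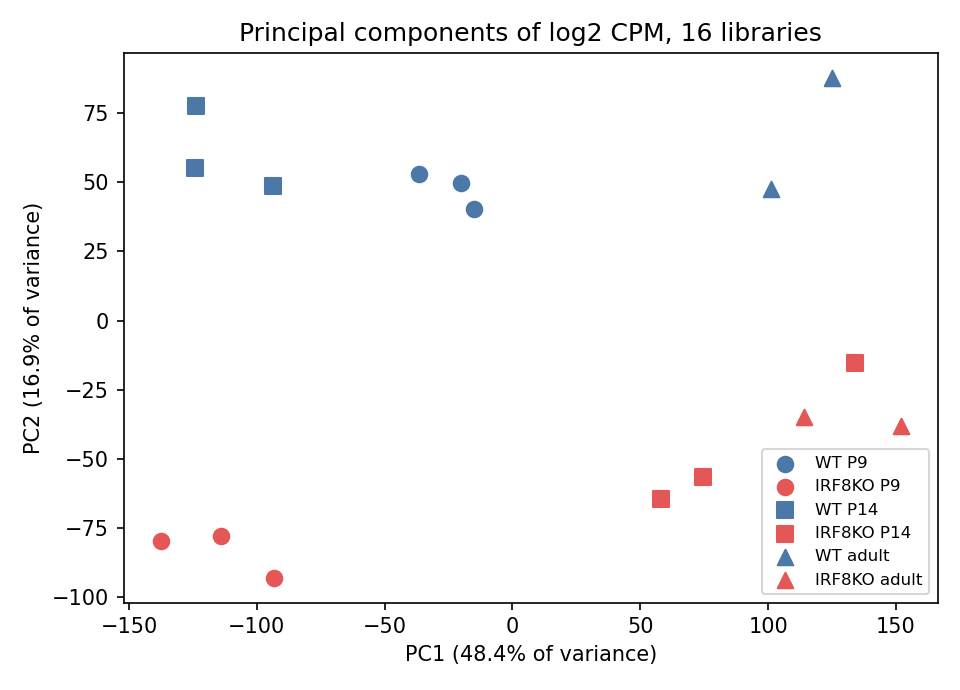
Principal component scores of the 16 libraries, coloured by genotype and shaped by age.

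Irf8 itself was read in every library, whichever genotype it was labelled with. At P9 the 3 WT libraries held 538.3, 714.7 and 639.4 CPM (counts scaled to library size), and the 3 labelled IRF8KO held 1021, 1089 and 883.4 CPM. At P14 WT libraries held 1215, 882.0 and 734.6 CPM against 603.0, 681.5 and 894.2 CPM. Adult WT libraries held 556.6 and 1178 CPM against 388.9 and 693.1 CPM. The log2 fold changes were 0.66 ± 0.32 (standard error, SE), -0.38 ± 0.32 and -0.68 ± 0.40, with adjusted p = 0.203, 0.395 and 0.744 (edgeR quasi-likelihood, Benjamini-Hochberg). No change of Irf8 passed at any age, the estimate being above 0 at P9 and below 0 at P14 and in adults. The gene was read in all 8 libraries labelled IRF8KO, and gene-level counts do not show which exons or which allele the reads come from, so the genotype is named here only as a label. Of the tested neighbours of Irf8 on chromosome 8, Gse1, Emc8 and Cox4i1 passed at no age. Mthfsd, a folate-binding enzyme homologue, was lower at P14 only (-0.81 ± 0.28, adjusted p = 0.0313, and 0.0587 to 0.0874 in 4 of 6 fits without 1 library). Gins2, which encodes a subunit of the replicative helicase complex, was also lower at P14 only (-2.18 ± 0.42, adjusted p = 0.000913), a value made uncertain by exons shared with Gse1 on the other strand.

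Transcripts of Spint1, Sall1 and Adgrg5 were missing from the P9 libraries labelled IRF8KO. Spint1 encodes a Kunitz-type inhibitor of cell-surface serine proteases, Sall1 a zinc-finger transcription factor that keeps microglia in their resident state, and Adgrg5 an adhesion G protein-coupled receptor. Among the higher genes were Pf4, Clec4n, Clec12a and Cd163, known from border-associated macrophages, the macrophages of the meninges and perivascular spaces. Pf4 encodes the chemokine platelet factor 4, Clec4n and Clec12a C-type lectin receptors, and Cd163 the haemoglobin scavenger receptor. Apoe, which encodes the main lipid carrier of the brain, was raised as well. Levels below are mean CPM ± SD over libraries, with the IRF8KO label first.

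Of 18295 genes tested at P9, 2855 changed (edgeR quasi-likelihood, Benjamini-Hochberg), 778 higher and 2077 lower in libraries labelled IRF8KO, and 6441 with voom. Spint1 had 0 reads against 251.8 ± 32.5 CPM, at least 3355-fold lower (adjusted p = 3.93e-08). Sall1 had 0 reads against 163.2 ± 21.9 CPM, at least 2217-fold lower (adjusted p = 4.67e-07), and Adgrg5 had 0 reads against 78.2 ± 22.1 CPM, at least 1037-fold lower. Npnt, which encodes the integrin ligand nephronectin, had 3 reads in the libraries labelled IRF8KO, a ratio of 1330 (95% counting interval 454.8 to 6452). Mrc2, a collagen receptor, was at 0.189 ± 0.177 against 112.6 ± 42.2 CPM (log2 fold change -9.09 ± 0.74). In the other direction Pf4 was at 3121 ± 950 against 2.503 ± 1.29 CPM (10.28 ± 0.73, adjusted p = 1.09e-07), Clec4n at 358.4 ± 89.6 against 0.311 ± 0.275 CPM (10.11 ± 0.94) and Clec12a at 71.8 ± 15.4 against 0.137 ± 0.237 CPM (9.06 ± 0.71). Vnn3, a pantetheinase, had 44.3 ± 2.31 CPM against 0 reads (at least 604-fold), Apoc4, an apolipoprotein, 34.4 ± 8.27 CPM against 0 (at least 463-fold), and Tlr8, a sensor of single-stranded RNA, 23.6 ± 15.7 CPM against 0 (at least 333-fold). Cd163 and Cd244a, a receptor of the SLAM family, had 1 WT read each, with ratios of 1617 (289.8 to 63900) and 3551 (637.0 to 140300). These genes, most chosen for it, did not overlap between genotypes.

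Gene lists written before the data were examined place these genes in context at P9. The homeostatic microglia list had 0 genes higher and 8 lower of 28 (12 lower when adjusted over the list alone), with a median log2 fold change of -0.86 (camera adjusted p = 3.1e-05, and adjusted p = 0.0767 with an estimated correlation). Adora3, an adenosine receptor, fell by 7.22 on the log2 scale, Slc2a5, the fructose transporter, by 3.06, and Sparc, a matrix-binding glycoprotein, by 2.57 (adjusted p = 4.17e-08, 4.2e-05 and 1.61e-05). Sall1 is also on this list. P2ry12, the ADP receptor of microglial processes, did not pass (173.5 ± 113.7 against 774.8 ± 277.7 CPM, adjusted p = 0.0537). Nor did Tmem119 (2909 ± 615 against 5270 ± 1123 CPM, adjusted p = 0.204). P2ry12 did pass with DESeq2 (adjusted p = 0.00848), with RLE factors (0.0426) and without library 3 of IRF8KO P9 (0.0323). The border-associated macrophage list rose with 11 of 14 genes higher and 0 lower (13 higher when adjusted over the list alone), with a median of 3.91 (camera adjusted p = 2.94e-18, and 7.87e-05 with an estimated correlation). Siglec1, the sialic acid receptor of tissue macrophages, rose by 4.53, Dab2, an endocytic adaptor, by 3.25, Cbr2, a carbonyl reductase, by 3.89, and Stab1, a scavenger receptor, by 1.54. Mrc1, the mannose receptor, was at 564.6 ± 305.5 against 128.1 ± 57.1 CPM and did not pass (adjusted p = 0.0564).

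Of 4 further lists at P9, 2 passed with the preset correlation and 0 with an estimated one. Interferon-stimulated genes had 9 higher and 2 lower of 26 (9 and 3 when adjusted over the list alone), with a median of 1.01 (camera adjusted p = 0.000185, and adjusted p = 0.246 with an estimated correlation). Rtp4, a chaperone of G protein-coupled receptors, rose by 2.61, Irf7, the amplifier of type I interferon production, by 1.98, Ifit3, an antiviral RNA-binding protein, by 2.173, and Oas2, an oligoadenylate synthetase, by 3.60. Mx1, an antiviral GTPase, fell by 4.83. The Ifit3 call was lost without library 1 of either genotype (adjusted p = 0.064 and 0.0629). The macrophage transcription factor list had 9 higher and 2 lower of 32 (the same when adjusted over the list alone), with a median of 0.46 (camera adjusted p = 0.0058, and adjusted p = 0.178 with an estimated correlation). Bhlhe40, a repressor that governs macrophage proliferation, rose by 5.92 and Batf3, a partner of IRF8 in dendritic cells, fell by 5.21 (adjusted p = 5.53e-06 and 1.26e-05). Ctsh, which encodes the lysosomal protease cathepsin H, was at 3.22 ± 0.21 against 590.9 ± 94.0 CPM (-7.52 ± 0.48, adjusted p = 3.93e-08). The lysosomal list as a whole did not pass, with 1 higher and 4 lower of 31 (2 and 8 when adjusted over the list alone) and a median of -0.38 (camera adjusted p = 0.175), although it passed without library 1 of WT P9 or of IRF8KO P9 (0.0246 and 0.0451). The disease-associated microglia list held changes in both directions, 6 higher and 5 lower of 26 (9 and 9 when adjusted over the list alone), with a median of -0.05 against a mean of 0.07 and an upward rank (camera adjusted p = 0.548). Apoe rose from 12920 ± 2945 to 76020 ± 20130 CPM (2.56 ± 0.51, adjusted p = 0.00213), Clec7a, the beta-glucan receptor, rose by 7.17, and Axl, a receptor for apoptotic cells, fell by 4.54.

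At P14 Spint1, Sall1 and Adgrg5 were again near or at 0 reads in libraries labelled IRF8KO, and transcripts of DNA replication were fewer than in WT. Mcm2, Mcm3 and Mcm5 encode subunits of the replicative helicase, and Ccne1 encodes cyclin E1, which starts S phase. Among the largest rises were the receptor genes Clec7a, Clec12a and Trem1, the last an amplifier of inflammatory signals. Transcripts of neurons, such as Snap25 and Syt1 of the synaptic vesicle machinery, were also far higher in libraries labelled IRF8KO.

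Of 18295 genes tested at P14, 6222 changed (edgeR quasi-likelihood, Benjamini-Hochberg), 4235 higher and 1987 lower in libraries labelled IRF8KO. The count was 9694 with voom, 3851 when only the groups compared were fitted and 3480 with reads outside genes as a covariate. Spint1 had 0 reads against 471.0 ± 97.4 CPM, at least 5379-fold lower (adjusted p = 5.77e-08). Sall1 was at 0.377 ± 0.198 against 184.5 ± 55.8 CPM (log2 fold change -8.99 ± 0.72), and Mrc2 at 0.479 ± 0.318 against 279.1 ± 89.2 CPM (-9.26 ± 0.72). Adgrg5 had 2 reads in the libraries labelled IRF8KO, a ratio of 1313 (95% counting interval 363.1 to 10850). Tnfrsf17, which encodes the receptor BCMA, had 0 reads against 26.7 ± 6.19 CPM (at least 304-fold lower), and Tns4, a focal adhesion protein, 0 reads against 14.02 ± 4.23 CPM (at least 159-fold lower). Clec12a was at 97.3 ± 25.1 CPM against 0 reads (at least 1143-fold, adjusted p = 3.18e-07), Clec7a at 89.0 ± 66.7 CPM against 0 (at least 1129-fold), Cd38, an NAD-consuming ectoenzyme, at 41.5 ± 23.3 CPM against 0 (at least 514-fold), Ms4a4a, a tetraspanning membrane protein, at 41.5 ± 8.16 CPM against 0 (at least 456-fold) and Trem1 at 32.7 ± 6.91 CPM against 0 (at least 366-fold). Gdf3, a TGF-beta family ligand, was at 475.3 ± 343.9 against 0.139 ± 0.130 CPM (11.57 ± 0.83, adjusted p = 1.06e-07). These genes, most chosen for it, did not overlap between genotypes.

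The homeostatic list was lower at P14, with 0 genes higher and 16 lower of 28 (17 lower when adjusted over the list alone) and a median of -1.15 (camera adjusted p = 2.41e-11, and adjusted p = 0.00671 with an estimated correlation). Cx3cr1, the fractalkine receptor, was at 867.3 ± 307.7 against 3127 ± 316 CPM (-1.85 ± 0.35, adjusted p = 0.000748), and Csf1r, the receptor on which microglial survival depends, at 11830 ± 1775 against 30780 ± 6747 CPM (-1.38 ± 0.37, adjusted p = 0.00902). Tmem119 (-1.40 ± 0.43, adjusted p = 0.0179) and P2ry12 (-2.10 ± 0.73, adjusted p = 0.0336) fell too, P2ry12 with 2 of 3 libraries labelled IRF8KO below all WT libraries and the other genes with 3 of 3. Leaving out 1 library ended the P2ry12 call in 4 of 6 fits (adjusted p = 0.0635 to 0.0902) and the Tmem119 call in 2 of 6 (0.058 and 0.0591). Cell cycle genes had 0 higher and 20 lower of 28 (20 lower when adjusted over the list alone), with a median of -1.82 (camera adjusted p = 5.24e-12, and 0.0159 with an estimated correlation). Mcm2 fell by 2.91, Mcm5 by 2.70, Ccne1 by 2.68 and Mcm3 by 2.67. At P9 the same list had 0 genes called in either direction and a median of -0.43 (camera adjusted p = 0.134, but 0.022 without library 1 of IRF8KO P9). Lysosomal genes were lower, 2 higher and 12 lower of 31 (2 and 12 when adjusted over the list alone), with a median of -0.64 (camera adjusted p = 8.35e-06, and adjusted p = 0.256 with an estimated correlation). Psap, the precursor of the saposins, fell by 1.90, Npc1, the lysosomal cholesterol exporter, by 1.60 and Ctsh by 6.76.

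The TGF-beta and cholesterol lists passed at P14 with the preset correlation only. The TGF-beta list, of which microglia depend on several members, had 0 higher and 3 lower of 13 (3 lower when adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.00789, and adjusted p = 0.246 with an estimated correlation). Acvrl1, a type I receptor of the family, fell by 4.42, Smad3, a signal transducer of TGF-beta, by 1.28 and Tgfb1 by 1.25. Without library 3 of the IRF8KO P14 group this list no longer passed (camera adjusted p = 0.0792). Cholesterol synthesis genes had 1 higher and 4 lower of 22 (1 and 2 when adjusted over the list alone), with a median of -0.52 (camera adjusted p = 0.0219, and adjusted p = 0.391 with an estimated correlation). This list lost its call without library 2 of WT P14 (camera adjusted p = 0.0599) and with fry (0.0692). Srebf2, the master regulator of the pathway, fell by 1.08 while Lss, lanosterol synthase, rose by 1.51, a call lost in 3 of 6 fits without 1 library (adjusted p = 0.0565 to 0.122). The list of LXR targets and lipid handling genes had 4 higher and 2 lower of 15 (the same when adjusted over the list alone) and did not pass (median 0.37, camera adjusted p = 0.527). Within it Apoe rose from 7506 ± 1440 to 135800 ± 86330 CPM (4.18 ± 0.54, adjusted p = 3.25e-05), Acaca, acetyl-CoA carboxylase, rose by 3.72 and Fasn, fatty acid synthase, fell by 1.33.

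Border-associated macrophage and interferon-stimulated genes were higher at P14 as at P9. Border-associated macrophage genes had 9 higher and 0 lower of 14 (10 higher when adjusted over the list alone), with a median of 3.33 (camera adjusted p = 8.35e-06, and 0.00671 with an estimated correlation). Pf4 was at 2092 ± 1102 against 1.52 ± 0.77 CPM (10.43 ± 0.75), Clec4n rose by 10.84 and Mrc1 by 3.33 (adjusted p = 0.00329). Interferon-stimulated genes had 15 higher and 1 lower of 26 (15 and 2 when adjusted over the list alone), with a median of 1.81 (camera adjusted p = 0.0219, and adjusted p = 0.45 with an estimated correlation). Isg15, a ubiquitin-like modifier, rose by 3.24, Ifit3 by 3.98 and Oas2 by 4.43 (2 of 3 libraries labelled IRF8KO above all WT), although without library 1 of the IRF8KO P14 group the list no longer passed (camera adjusted p = 0.166). The disease-associated list had 10 higher and 6 lower of 26 (10 and 7 when adjusted over the list alone). Its median was 0.28 and its mean 0.85, while the test ranked it downward (camera adjusted p = 0.917). Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages, rose by 5.11, Csf1, the ligand of CSF1R, rose by 1.95 and Axl fell by 3.79. The transcription factor list had 7 higher and 5 lower of 32 (the same when adjusted over the list alone) and did not pass (median 0.39 and mean 0.02 against a downward rank, camera adjusted p = 0.45), with Bhlhe40 up by 5.60 and Batf3 down (-7.66 ± 0.71).

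**Figure D2:**
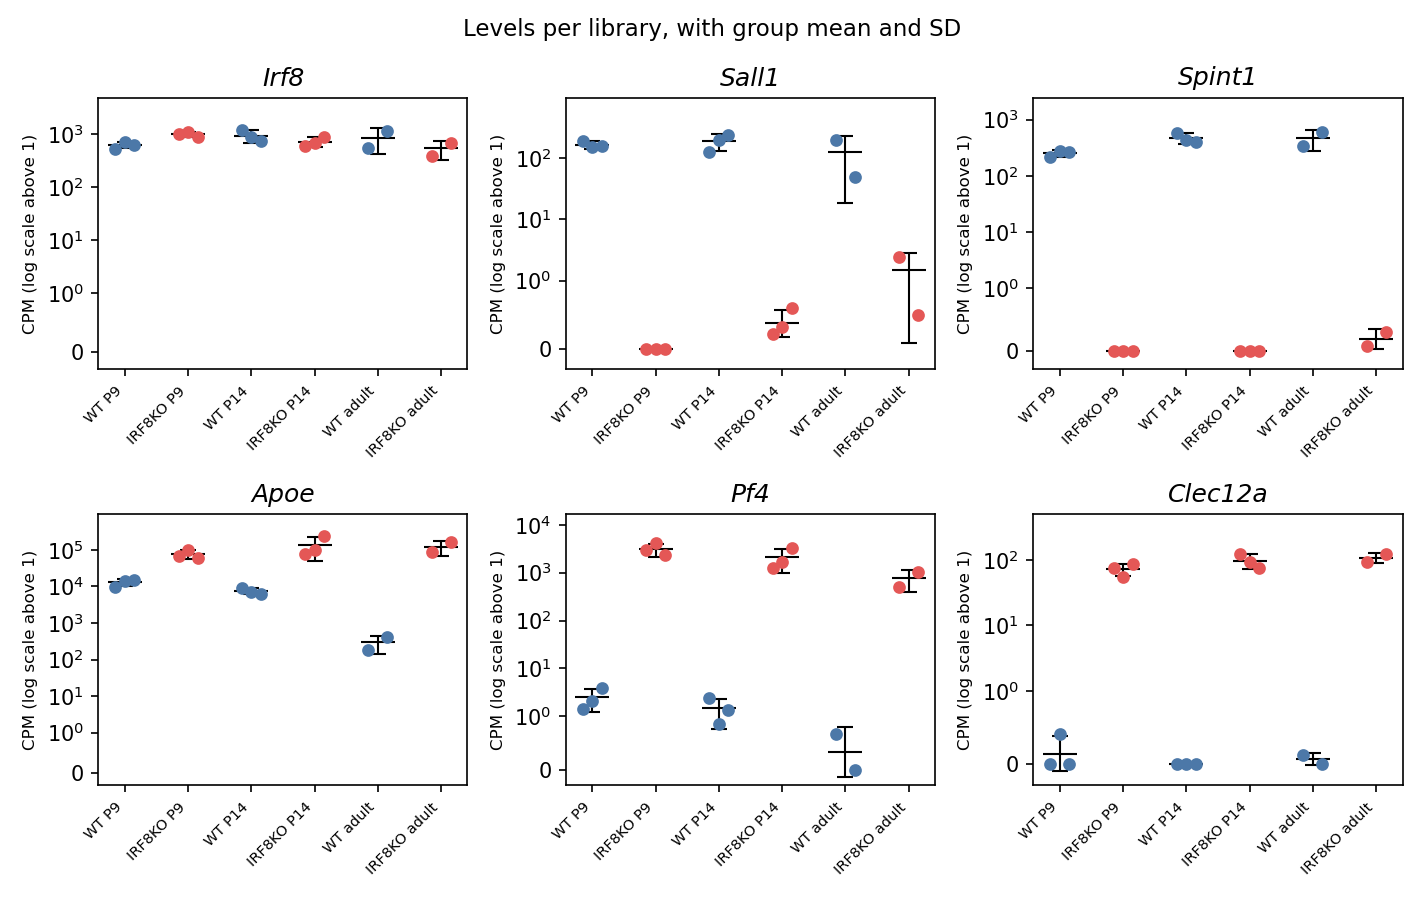
CPM of Irf8, Sall1, Spint1, Apoe, Pf4 and Clec12a in each library, with group means ± SD, on a scale that is logarithmic above 1.

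Adult libraries labelled IRF8KO still lacked Spint1 and held Apoc1, Apoc4 and C3, hardly read in adult WT libraries. Apoc1 and Apoc4 lie beside Apoe in an apolipoprotein cluster. C3 encodes the central complement component and Ms4a7 a membrane protein of peripheral and border-associated macrophages. Among the genes lost were Tlr12, a sensor of microbial profilin, Upk1b, a uroplakin, and Il7r, the interleukin-7 receptor. Among the higher genes were Tnf and the genes of the neutrophil chemokines, Cxcl1 and Cxcl2, with calls that partly hung on single libraries.

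Of 18295 genes tested in adults, 575 changed (edgeR quasi-likelihood, Benjamini-Hochberg), 302 higher and 273 lower in libraries labelled IRF8KO. This count fell to 339 without library 1 and to 320 without library 2 of the adult IRF8KO group, and was 382 with voom, 881 with DESeq2 and 930 with reads outside genes as a covariate. Apoc1 was at 1077 ± 520 CPM against 0 reads (at least 8456-fold, adjusted p = 4.31e-07), and Apoc4 at 104.2 ± 26.8 CPM against 0 (at least 844-fold). Ms4a7 had 1 WT read, a ratio of 5957 (95% counting interval 1069 to 235300), and C3 had 1 WT read, a ratio of 2784 (499.3 to 110000). Gdf3 was at 358.4 ± 148.8 against 0.229 ± 0.324 CPM (log2 fold change 10.95 ± 1.00), and Pf4 at 758.8 ± 362.2 against 0.335 ± 0.474 CPM (10.84 ± 0.96, adjusted p = 4.28e-06). Spint1 was at 0.182 ± 0.162 against 467.8 ± 192.7 CPM (-11.39 ± 0.66, adjusted p = 6.88e-07). Tlr12 was at 0.929 ± 0.894 against 423.7 ± 244.1 CPM (-8.74 ± 1.04), Upk1b at 0.451 ± 0.062 against 170.2 ± 62.5 CPM (-8.54 ± 0.81) and Sall1 at 1.47 ± 1.38 against 122.7 ± 104.2 CPM (-6.32 ± 0.75). Tns4 had 0 reads against 19.6 ± 3.52 CPM (at least 168-fold lower), and Il7r 0 reads against 21.2 ± 23.8 CPM (at least 218-fold lower). These genes, most chosen for it, did not overlap between genotypes, which 2 libraries per group reach easily by chance.

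The adult homeostatic list had 1 gene higher and 6 lower of 28 (1 and 8 when adjusted over the list alone), with a median of -0.95 (camera adjusted p = 2.8e-12, and adjusted p = 0.00671 with an estimated correlation). Siglech, a microglial sialic acid receptor, fell by 1.40 and Fcrls, an Fc receptor-like scavenger, rose by 1.95 (adjusted p = 0.0154 and 0.0118). The Siglech call was lost without library 1 of the adult IRF8KO group (adjusted p = 0.148), and the Fcrls call without library 1 of the WT adults or library 2 of that group (0.0829 and 0.127). P2ry12 was at 173.6 ± 64.1 against 517.7 ± 536.5 CPM and did not pass (adjusted p = 0.693), nor did Tmem119 (adjusted p = 0.625) or Cx3cr1 (adjusted p = 0.567). Border-associated macrophage genes had 11 higher and 0 lower of 14 (11 when adjusted over the list alone), with a median of 5.61, or 5.08 with zero-read genes at their bound (camera adjusted p = 1.93e-22, and 5.71e-05 with an estimated correlation). Mrc1 was at 130.3 ± 50.7 against 4.09 ± 4.81 CPM (4.93 ± 1.03), Dab2 rose by 6.02 and Siglec1 by 4.98. Mrc1 lost its call without library 2 of the WT adults or library 1 of the adult IRF8KO group (adjusted p = 0.124 and 0.0634). Interferon-stimulated genes had 5 higher and 0 lower of 26 (8 higher when adjusted over the list alone), with a median of 1.60 (camera adjusted p = 3.56e-09, and adjusted p = 0.0799 with an estimated correlation). Rtp4 rose by 3.66, Oasl2, a 2'-5' oligoadenylate synthetase-like protein, by 3.76, Ifit3 by 3.25 and Oas2 by 6.70. Without library 2 of the WT adults Oasl2, Ifit3 and Oas2 did not pass (adjusted p = 0.228, 0.0671 and 0.066), nor did Ifit3 without library 1 of that group (0.0512) or Oasl2 without library 1 or 2 of the adult IRF8KO group (0.0533 and 0.0759). The LXR target and lipid handling list had 3 higher and 0 lower of 15 (3 when adjusted over the list alone), with a median of 0.54 (camera adjusted p = 0.00459, and adjusted p = 0.178 with an estimated correlation). Apoe rose from 292.2 ± 153.1 to 122700 ± 53100 CPM (8.71 ± 0.82, adjusted p = 7.83e-06), Acaca by 3.14 and Plin2, a coat protein of lipid droplets, by 1.58, its call lost in 3 of 4 fits without 1 library (adjusted p = 0.0514 to 0.365). At P9 that list had 4 higher and 1 lower of 15 (the same when adjusted over the list alone), with a median of 0.66 (camera adjusted p = 0.0253, and adjusted p = 0.246 with an estimated correlation), with Abcg1, a cholesterol exporter, up by 1.28, but not without library 1 of either genotype (adjusted p = 0.0768 and 0.0566). The list lost its call at P9 without library 3 of WT P9 (camera adjusted p = 0.0521), and in adults without library 1 of the WT group (0.132) or library 2 of the IRF8KO group (0.079).

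The inflammatory and lysosomal lists passed in adults with the preset correlation only. The inflammatory list had 6 higher and 1 lower of 25 (7 and 1 when adjusted over the list alone), with a median of 0.09 (camera adjusted p = 0.00799, and adjusted p = 0.189 with an estimated correlation). The call was lost without library 2 of the WT adults (camera adjusted p = 0.0971). Tlr2, a lipoprotein sensor, rose by 1.63 and Tnf by 3.72, and Cxcl1 and Cxcl2 were at least 28.7-fold and 32.8-fold higher against 0 WT reads. Il6 had 0 reads against 4.90 ± 5.64 CPM, a mean carried unevenly by the WT libraries. Tlr2 lost its call without library 2 of the WT adults (adjusted p = 0.166), Tnf without that library or library 2 of the adult IRF8KO group (0.0792 and 0.0835), Cxcl2 without library 1 of the WT adults (0.0518) and Il6 in 3 of 4 fits without 1 library (0.213 to 0.279). The immediate early list, which dissociation can raise, was higher in the same libraries (median 1.54, camera adjusted p = 1.92e-06, and adjusted p = 0.218 with an estimated correlation), and the 2 lists were not told apart here. At P9 the inflammatory list had 4 higher and 4 lower (5 and 6 when adjusted over the list alone; median 0.19, camera adjusted p = 0.25), and at P14 6 higher and 1 lower (5 and 1; median 0.35, camera adjusted p = 0.83). The adult lysosomal list had 0 higher and 1 lower of 31 (4 lower when adjusted over the list alone), with a median of -0.52 (camera adjusted p = 1.87e-07, and adjusted p = 0.223 with an estimated correlation), and Ctsh fell by 4.71. The disease-associated list had 7 higher and 3 lower of 26 (8 and 4 when adjusted over the list alone), with a median of -0.11 against a mean of 0.71 and an upward rank (camera adjusted p = 0.324). It passed without library 2 of the WT adults (0.0367) or library 1 of the adult IRF8KO group (0.00312), and its rank turned downward without either of the other 2 libraries (0.745 and 0.74). Cst7, cystatin F, rose by 3.47, Csf1 by 2.87, and Axl fell by 4.02. Trem2, the lipid receptor upstream of many disease-associated genes, passed at no age (adjusted p = 0.502, 0.344 and 1). Cell cycle genes had 1 higher and 0 lower of 28 (the same when adjusted over the list alone; median 0.04, camera adjusted p = 0.85), the exception being Bub1b of the spindle checkpoint, which rose by 3.24 but not without library 2 of either genotype (adjusted p = 0.109 and 0.1). The transcription factor list had 5 higher and 2 lower (6 and 3 when adjusted over the list alone; median 0.20, camera adjusted p = 0.214), with Irf4, a relative of IRF8, up by 3.46 but not without library 2 of either genotype (adjusted p = 0.137 and 0.108).

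Some lists of function passed at few ages or at none. Phagocytic and Fc receptor genes, 21 tested, had 2 higher and 1 lower at P9 (2 and 1 when adjusted over the list alone), 4 and 4 at P14 (4 and 4) and 4 and 2 in adults (4 and 3). Their medians were 0.06, -0.17 and -0.02, and camera adjusted p = 0.261, 0.27 and 0.85, with means of 0.22 at P14 (test downward) and 0.66 in adults (test upward) opposed to the medians. C3ar1, the receptor for C3a, was called higher at all 3 ages (1.11, 1.52 and 2.35), as was Cd300lf, a phosphatidylserine receptor (2.97, 2.70 and 2.65). The P9 call of C3ar1 was lost without library 1 or 3 of IRF8KO P9 (adjusted p = 0.0747 and 0.0763), and the adult call of Cd300lf in 3 of 4 fits without 1 library (0.0599 to 0.348). Fcgr1, the high-affinity IgG receptor, fell at P14 (-1.43 ± 0.30, adjusted p = 0.00164). The TGF-beta list had 1 gene higher and 1 lower at P9 (1 and 1 when adjusted over the list alone; median 0.14, mean -0.09, upward rank, camera adjusted p = 0.491) and 1 lower in adults (1 when adjusted over the list alone; median -0.10, camera adjusted p = 0.323, but 0.0316 without library 2 of the WT adults), where Acvrl1 fell by 5.84. Cholesterol synthesis genes had 2 lower at P9 (2 when adjusted over the list alone; median -0.25, camera adjusted p = 0.512). In adults 1 was higher (2 when adjusted over the list alone; median 0.11, camera adjusted p = 0.171, but 0.0225 without library 2 of the WT adults).

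**Figure D3:**
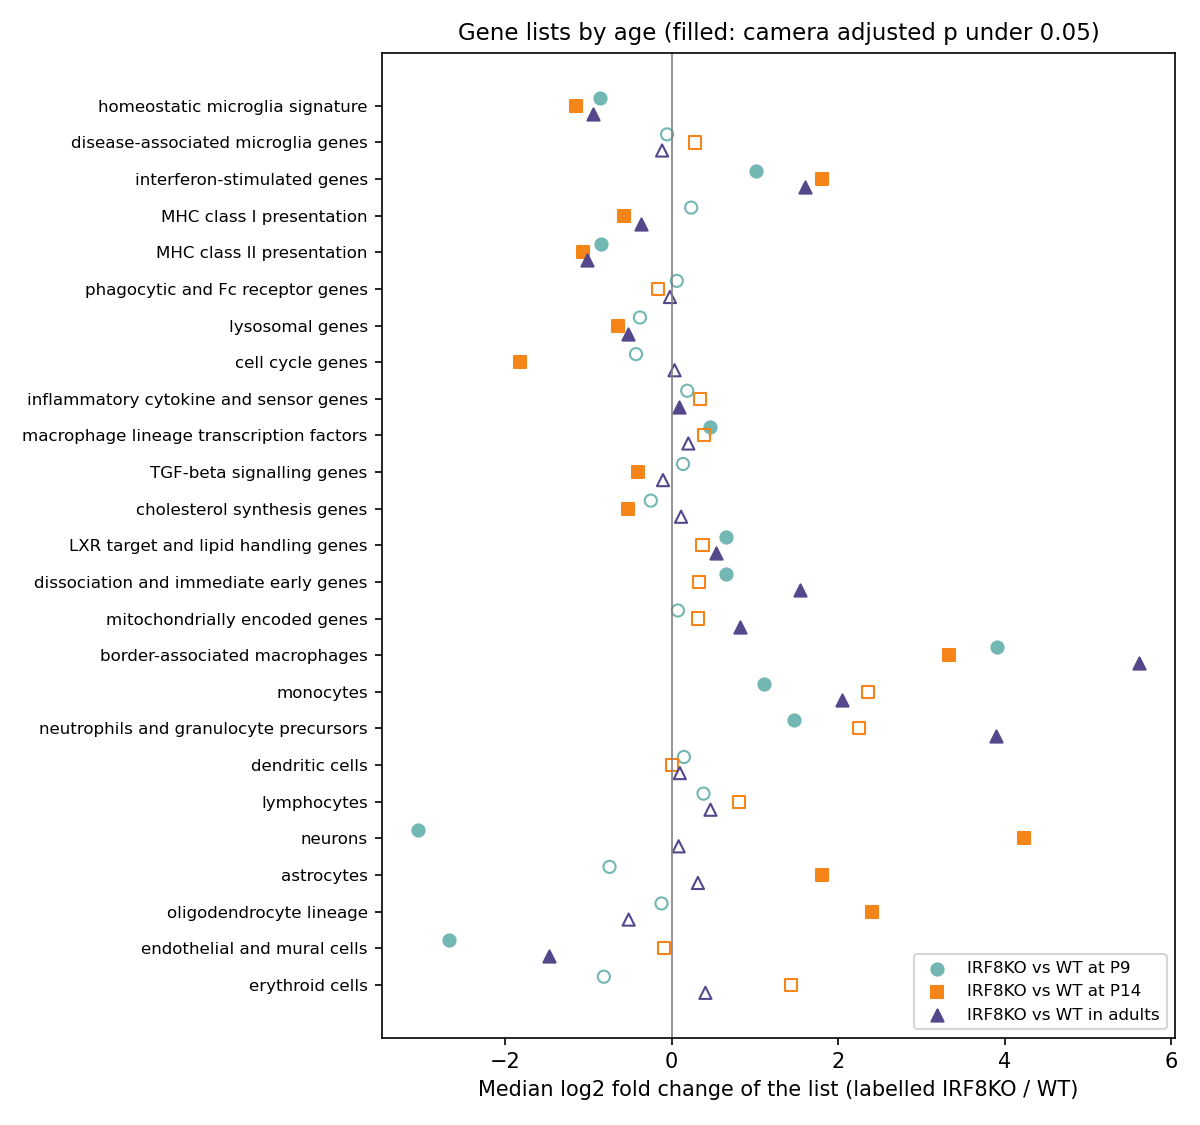
Median log2 fold change of each gene list at each age, filled where the camera adjusted p-value is below 0.05.

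A shared core stood out against effects that reversed with age. Spint1, Adgrg5 and Sall1 were lower at all 3 ages, together with Slamf8, a receptor of the SLAM family, and Pdcd1, which encodes the inhibitory receptor PD-1. In all, 203 genes were higher and 195 lower at each of the 3 ages, where 2.97 and 3.37 would be met if the calls were independent. These numbers fell to 116 higher without library 2 of the adult IRF8KO group and to 93 lower without library 1 of that group. Averaged over the ages, 2642 genes changed (edgeR quasi-likelihood, Benjamini-Hochberg), 1271 higher and 1371 lower. Over all 18295 genes, fold changes at P9 correlated with those in adults (r = 0.337 ± 0.148, jackknife SE), as did those at P14 with those in adults (r = 0.356 ± 0.198), more strongly among the 8015 genes with a mean of at least 10 CPM (r = 0.621 and 0.638). Between P9 and P14 the correlation was negative (r = -0.228 ± 0.0948), yet positive (r = 0.285) among those 8015 genes. The reversal came from genes lower at P9 and higher at P14, 1337 where 480.8 would be met by chance, against 1 gene that went the opposite way.

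The interaction test names the genes behind that reversal. Meg3, a maternally expressed long non-coding RNA abundant in neurons, was at 8.61 ± 4.95 against 197.2 ± 25.7 CPM at P9 and at 905.3 ± 554.3 against 21.02 ± 13.3 CPM at P14. Its genotype effect differed by 9.94 ± 0.85 on the log2 scale between the ages (adjusted p = 1.3e-06). Synaptic genes followed, with differences of 8.09 for Syt1, 9.10 for Snap25 and 6.63 for Slc17a7, the vesicular glutamate transporter, and so did Rbfox3, a neuronal splicing factor (7.55), and Map2, of dendritic microtubules (7.27). In all, 3857 genes had a genotype effect that differed between P9 and P14 (edgeR quasi-likelihood, Benjamini-Hochberg), 3334 upward and 523 downward. The count was 8796 with voom (5290 and 3506), 1955 with a filter at 5 CPM (1599 and 356) and 2437 with reads outside genes as a covariate (2354 and 83), and without 1 library the downward part ran from 60 to 1121. Among the downward genes were Mcm2 (-2.40 ± 0.50, adjusted p = 0.0019), Mcm5 (-2.27 ± 0.55) and Tgfb1 (-1.70 ± 0.45, adjusted p = 0.073 and 0.0503 without library 1 of WT P9 or of IRF8KO P9). For Pf4 no difference was called (0.15 ± 0.75, adjusted p = 0.911), and its sign turned in 3 fits without 1 library. The neuron list had 0 higher and 10 lower of 11 at P9 (11 lower when adjusted over the list alone), with a median of -3.04 (camera adjusted p = 1e-06, and adjusted p = 0.246 with an estimated correlation). At P14 it had 10 higher and 0 lower (11 when adjusted over the list alone), with a median of 4.23 (camera adjusted p = 2.32e-05, and adjusted p = 0.329 with an estimated correlation). In adults 0 were called, also when adjusted over the list alone (median 0.08, mean -0.03, upward rank, camera adjusted p = 0.858).

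**Figure D4:**
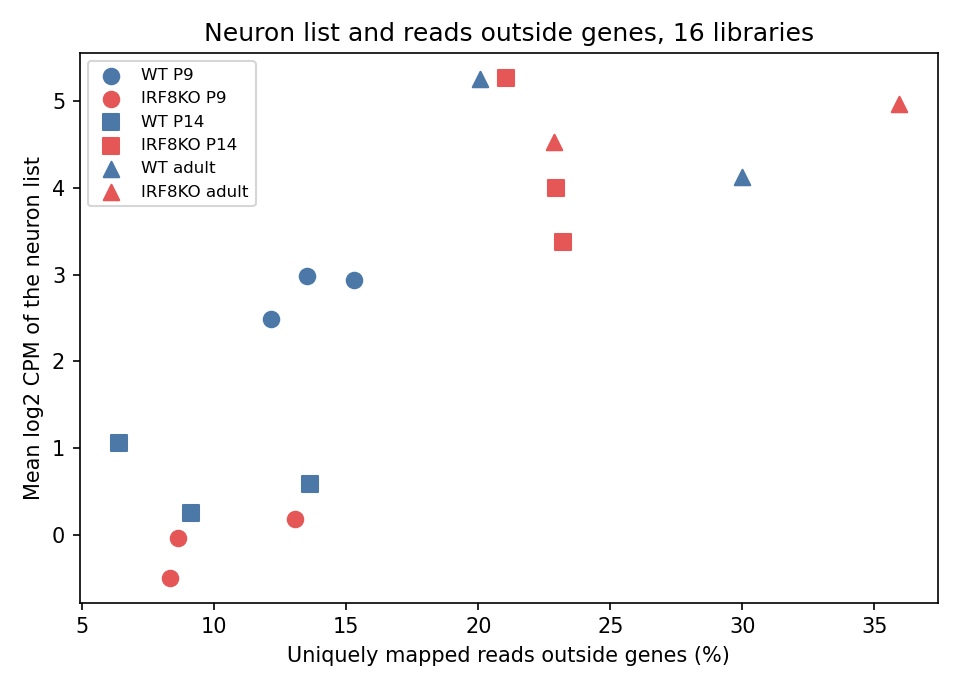
Mean log2 CPM of the neuron list against the percentage of uniquely mapped reads outside genes in the 16 libraries.

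Between P14 and the adult stage 1504 genes had a genotype effect that differed (edgeR quasi-likelihood, Benjamini-Hochberg), 232 upward and 1272 downward. The count fell to 961 without library 2 of WT P14, 949 without library 2 of WT adults, and 647 and 149 without library 1 or 2 of the adult IRF8KO group, and was 2323 with DESeq2. Apoe widened its difference (4.54 ± 0.80, adjusted p = 0.00346), as did Dab2 (2.70 ± 0.81), and Fcrls went from an estimate of -0.69 at P14 to one of 1.95 in adults (2.64 ± 0.53). Replication genes lost their deficit, Mcm2 by 2.48 ± 0.57 (adjusted p = 0.0119) and Cdk1, the mitotic kinase, by 2.35 ± 0.57, as did Cd74, the MHC class II chaperone (2.51 ± 0.64, adjusted p = 0.023). Meg3 moved the other way (-5.31 ± 0.86), together with Mbp, a structural gene of myelin (-2.43 ± 0.59). Without 1 library Dab2 was lost in 7 of 10 fits (adjusted p = 0.0564 to 0.268). Without library 2 of the adult IRF8KO group Mcm2 (0.125), Cdk1 (0.0876), Cd74 (0.0842) and Mbp (0.0714) were lost, as were Cdk1 (0.0766) and Cd74 (0.084) without library 1 of the WT adults and Mbp (0.0817) without library 1 of the adult IRF8KO group.

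Between P9 and P14 WT libraries had falling levels of Gpnmb, Spp1, which encodes osteopontin, Lpl, lipoprotein lipase, and Fabp5, a fatty acid carrier. Selplg, the selectin ligand, and Sparc, both of the homeostatic signature, were called higher. In all, 785 genes changed (edgeR quasi-likelihood, Benjamini-Hochberg), 85 higher and 700 lower, a count that depended on single libraries and fell to 116 without library 2 of WT P14, 249 without library 3 of WT P9, 380 and 429 without libraries 3 and 1 of WT P14, and 466 without library 2 of WT P9. It was 1333 without a filter, 1491 with DESeq2 and 2930 with voom. Gpnmb fell by 4.42, Spp1 by 2.76, Lpl by 2.09 and Fabp5 by 1.67 (adjusted p = 0.00433, 0.0118, 0.0163 and 0.0193). Selplg rose from 2486 ± 481 to 7996 ± 1894 CPM (1.69 ± 0.38, adjusted p = 0.0193), Sparc by 1.06 and Hs3st2, a heparan sulfate sulfotransferase, by 2.78. Sparc lost its call without any 1 of the 6 libraries (adjusted p = 0.063 to 0.171), Selplg in 4 of 6 such fits (0.0668 to 0.0753), Fabp5 in 4 (0.0546 to 0.0993) and Lpl in 2 (0.0558 and 0.0773). The disease-associated list had 0 higher and 4 lower (7 lower when adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.0351, and adjusted p = 0.643 with an estimated correlation), and the LXR target and lipid handling list 0 higher and 2 lower (3 lower; median -0.41, camera adjusted p = 0.15). The neuron list had 0 higher and 5 lower of 11 (9 lower when adjusted over the list alone), with a median of -2.54 (camera adjusted p = 1.08e-06, and adjusted p = 0.468 with an estimated correlation). Meg3 fell by 3.23, Mapt, which encodes tau, by 3.91 and Snhg11, a host gene of small nucleolar RNAs expressed in brain, by 4.20. The homeostatic list had 2 higher and 0 lower (5 higher when adjusted over the list alone), with a median of 0.62 (camera adjusted p = 2.19e-09, and 0.021 with an estimated correlation). Cell cycle genes had a median of -1.02 with 0 called singly (camera adjusted p = 1.12e-08, and adjusted p = 0.0501 with an estimated correlation).

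Libraries labelled IRF8KO changed more over the same days, with 4337 genes called (edgeR quasi-likelihood, Benjamini-Hochberg), 3363 higher and 974 lower. The count was 9966 with voom, 2562 with a filter at 5 CPM and 2388 when only the groups compared were fitted. Replication and mitosis genes fell: Dtl, a licensing ubiquitin ligase adaptor, by 3.92, Uhrf1, which maintains DNA methylation, by 3.57, Mcm2 by 3.04 and Birc5, survivin, by 2.94 (adjusted p = 0.0005, 0.00012, 2.9e-05 and 5.56e-05). The cell cycle list had 0 higher and 23 lower (26 lower when adjusted over the list alone), with a median of -2.45 (camera adjusted p = 7.84e-20, and 0.00446 with an estimated correlation). The neuron list had 10 higher and 0 lower of 11 (10 when adjusted over the list alone), with a median of 5.55, or 5.43 with zero-read genes at their bound (camera adjusted p = 2.19e-07, and adjusted p = 0.441 with an estimated correlation). Meg3 rose by 6.71 and Kcnc1, a potassium channel of fast-spiking neurons, by 8.32. Of the 630 genes called over these days in both genotypes 94.6% moved in opposite directions, and the fold changes correlated at r = -0.577.

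From P14 to the adult stage WT libraries lost cell cycle transcripts and much of their Apoe. In all, 4950 genes changed (edgeR quasi-likelihood, Benjamini-Hochberg), 3596 higher and 1354 lower. The count was 3033 with a filter at 5 CPM, 2906 when only the groups compared were fitted and 2733 with reads outside genes as a covariate. Apoe fell by 4.68 to 292.2 ± 153.1 CPM (adjusted p = 0.000107), Fcrls by 3.04, Gpx3, extracellular glutathione peroxidase, by 6.38 and Htra3, a serine protease, by 6.06. Rrm2, of nucleotide synthesis, fell by 5.96 and Cdk1 by 4.78, and the cell cycle list had 0 higher and 22 lower (25 lower when adjusted over the list alone; median -3.02, camera adjusted p = 4.9e-16, and 0.00728 with an estimated correlation). H2-Ab1, an MHC class II chain, rose by 2.68 and Axl by 2.172, the former not without library 2 of the WT adults (adjusted p = 0.0651). Meg3 rose by 5.81, and the neuron list had 10 higher and 0 lower (11 when adjusted over the list alone; median 4.37, camera adjusted p = 3e-06, and adjusted p = 0.341 with an estimated correlation). Effects of the label at P9 ran against these changes (r = -0.491, and -0.306 among genes of at least 10 mean CPM), with 1377 genes lower at P9 in libraries labelled IRF8KO and higher in WT adults than at P14. Neuronal transcripts such as Meg3 are among them.

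Libraries labelled IRF8KO changed in 53 genes from P14 to the adult stage (edgeR quasi-likelihood, Benjamini-Hochberg), 30 higher and 23 lower. The count fell to 18 without either library of the adult IRF8KO group and to 28 without library 2 of IRF8KO P14, and it hung on the method, with 6 when only the groups compared were fitted, 164 with reads outside genes as a covariate, 199 with DESeq2 or without a filter and 760 with voom. Pmp22, a peripheral myelin protein, rose from 0.713 ± 0.489 to 80.0 ± 6.79 CPM (6.78 ± 0.52, adjusted p = 4.05e-06), Jag1, a Notch ligand, by 5.32 and H2-Eb1, an MHC class II chain, by 5.67. Cfp, properdin of the alternative complement pathway, fell by 3.88, Cbr2 by 3.40 and Ms4a4a by 3.02. Of the immediate early genes 4 passed, among them Fos, up by 5.21, Nr4a1 by 3.72 and Btg2 by 2.83, and their list had 0 lower (11 higher and 1 lower when adjusted over the list alone; median 1.48, camera adjusted p = 6.27e-13, and adjusted p = 0.0584 with an estimated correlation). Without 1 library Fos lost its call in 5 of 5 fits (adjusted p = 0.0518 to 0.199), H2-Eb1 in 3 (0.0526 to 0.068), Nr4a1 in 2 (0.1 and 0.294) and Ms4a4a in 2 (0.226 and 0.068). Without library 1 of the adult IRF8KO group Jag1, Cfp and Cbr2 were lost (0.123, 0.0833 and 0.177).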

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

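The tests of genomic DNA, scaling, border macrophages, monocytes and overlapping genes, the regroupings and the comparison of reads outside genes were chosen only after results were seen, while the comparisons between ages, the comparison of neuron genes between libraries and the test for label swaps were set before.

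Neuronal transcripts were lower at P9 and higher at P14 in libraries labelled IRF8KO, and at P14 the astrocyte and oligodendrocyte lists were higher as well (medians 1.81 and 2.41, camera adjusted p = 0.0398 and 0.0474, but 0.368 and 0.53 with an estimated correlation). RNA of neurons carried into the sorted samples is a candidate source, although sorting was for microglia. Beyond the group means the 11 genes of the neuron list rose and fell together from library to library (mean pairwise r = 0.613, against a highest value of 0.393 in 1000 sets of genes of equal abundance), which fits such carry-over and would also fit a shared neuronal programme. The most abundant, Meg3, stood at 905.3 CPM on average in libraries labelled IRF8KO at P14, and 6 of the 11 genes reached 10 CPM on average over the 8 WT libraries while 0 belong to another list. Genomic DNA is excluded by olfactory and vomeronasal receptor genes, whose gain per kilobase was at most 0.000309 of that of the neuron list, and scaling by medians of at least 3.14 in absolute log2 value under other factors.

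Border-associated macrophage genes were higher in libraries labelled IRF8KO at all 3 ages, 8 of the 14 list genes at every age, while 5 of 14 reached 10 CPM on average over the 8 WT libraries and 0 belong to another list. Border macrophages rich in Lyve1 that passed the sort for microglia are excluded as the source, because Lyve1 reached at most 0.144% of Pf4, which stood at 502.6 to 4156 CPM. Monocytes rich in Ly6c2, Ccr2, Plac8 and Chil3 are excluded, as these summed to at most 0.234% of Pf4. Class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1 summed to at most 2.09% of Pf4 at P9 and P14, but 21.8% to 36.3% in adults. Their median fold changes were -0.777 ± 0.936, -1.68 ± 0.734 and 0.0457 ± 0.667 by age (jackknife SE). At P14 both argue against class II-high border macrophages, at P9 only the share. They stay open in adults. So do, at each age, monocytes low in the 4 monocyte genes, border macrophages low in Lyve1 and class II genes, and microglia that express border genes.

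Irf8 was read in all 8 libraries labelled IRF8KO, and no change of it passed. A swap of labels between genotypes within an age is excluded, since 16 of 16 libraries lay on the side of their own label by genes called at the other 2 ages, although a swap of all labels at once is not. Reads of an overlapping gene are excluded, because 0 exon bases of Irf8 are covered by another gene. A targeted allele that is still transcribed was not tested and stays open, and the construct is not given in the sources used here.

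Genes whose genotype effect differed between ages numbered 3857 from P9 to P14 and 1504 from P14 to adults (edgeR quasi-likelihood, Benjamini-Hochberg). From P9 to P14 the lists that differed by camera had median differences of 7.55 (neuron), 2.99 (astrocyte), 2.24 (erythroid), -1.36 (cell cycle), -0.878 (MHC class I), -0.829 (immediate early), -0.471 (TGF-beta), -0.286 (homeostatic), -0.27 (transcription factors) and -0.259 (lysosome). With an estimated correlation none of these lists passed, the lowest adjusted p being 0.119 for the cell cycle. From P14 to adults the medians were -4.34 (neuron), -2.65 (oligodendrocyte), -2.19 (astrocyte), 2.02 (cell cycle), 1.6 (border macrophages), 1.05 (immediate early), 0.537 (cholesterol), 0.269 (TGF-beta), 0.24 (homeostatic), 0.104 (transcription factors) and -0.0334 (phagocytic). With an estimated correlation the cell cycle list alone still passed (adjusted p = 0.0298).

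Single genes with the largest such differences and more than 3 reads in each group were Snhg11 (12.4) and Tgm2 (-5.2) from P9 to P14, and Pmp22 (5.84), Qpct (5.7) and Ptger3 (5.63) from P14 to adults. Snhg11 is a neuronal host gene, Tgm2 a transglutaminase of macrophages, Pmp22 a myelin protein, Qpct a glutaminyl cyclase and Ptger3 a prostaglandin E2 receptor. Reads outside genes averaged 22.4% of uniquely mapped reads in IRF8KO P14, above the other P9 and P14 groups (9.71% to 13.7%) and below the adult groups (25.03% and 29.4%).

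Regrouping tested the counts against chance. The counts were 2855 genes at P9, 6222 at P14, 785 in WT from P9 to P14 and 4337 in libraries labelled IRF8KO. Each was reached by 1 of 10 splits (highest other 0). The 11 P9 and 12 P14 lists were reached by 2 and 1 of 10. Splits with 0 genes called gave up to 13 and 11 lists, so list counts say little of genotype. In these 6 designs splits are too few to exclude chance. For the averaged effect 2642 genes were reached by 1 of 100 regroupings (highest other 829), so chance is excluded. For P14 minus P9 the real grouping alone among 100 reached 3857 (highest other 2897). Regrouping also breaks the genotype effect both ages share, so it cannot isolate an age difference.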

How the results depend on the processing

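The covariate on reads outside genes, every alternative for genes shared by the 3 ages, and comparisons without a library they do not contain were chosen only after results were seen, and the other alternatives were set before.

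With voom and quality weights more genes were called at P9 (6441), at P14 (9694), for P14 minus P9 (8796), in WT from P9 to P14 (2930), in libraries labelled IRF8KO from P9 to P14 (9966) and from P14 to adults (760), and fewer in adults (382). DESeq2 called more in adults (881), for adult minus P14 (2323), in WT from P9 to P14 (1491) and in libraries labelled IRF8KO from P14 to adults (199). Without a filter WT from P9 to P14 gave 1333 and libraries labelled IRF8KO from P14 to adults 199. A filter at 5 CPM gave 1955 for P14 minus P9, 2562 in libraries labelled IRF8KO from P9 to P14 and 3033 in WT from P14 to adults. A fit of only the groups compared gave 3851 at P14, 2388 in libraries labelled IRF8KO from P9 to P14, 2906 in WT from P14 to adults and 6 in libraries labelled IRF8KO from P14 to adults. With the share of reads outside genes as a covariate, P14 gave 3480, adults 930, P14 minus P9 2437, WT from P14 to adults 2733 and libraries labelled IRF8KO from P14 to adults 164. The cause was not tested for any of these shifts, and 133 other gene counts stayed the same while 40 moved.

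Among genes of at least 10 mean CPM the correlation of genotype effects between P9 and P14 reversed to 0.285, and those of P9 with adults and of P14 with adults moved to 0.621 and 0.638. The adult effect against WT from P9 to P14 moved to -0.246, and the P9 effect against WT from P14 to adults to -0.306. The cause was not tested.

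With an estimated correlation, 1 list stayed called at P9, 3 at P14 and 2 in adults, against 11, 12 and 13 with the preset value and 14, 16 and 11 with fry. Fry added lysosome, cell cycle and astrocyte lists at P9 (adjusted p = 0.0475, 0.019 and 0.0305), inflammatory, LXR, monocyte, neutrophil and lymphocyte lists at P14 (0.00387 to 0.019) and lymphocytes in adults (0.0327), and dropped cholesterol at P14 (0.0692) and MHC class I, mitochondrial and vascular lists in adults (0.285, 0.0985 and 0.0931). Under fry the direction reversed for disease-associated genes at P9 (adjusted p = 0.779) and P14 (0.417), lymphocytes at P9 (0.176), immediate early genes at P14 (0.92) and dendritic cells at P14 (0.728). Of single list results 596 stayed the same, 63 grew weaker, 21 stronger and 20 reversed, each reversal in a list that had not passed.

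Leaving out each library in turn gave 320 to 738 genes in adults, 149 to 1817 for adult minus P14, 116 to 1128 in WT from P9 to P14 and 18 to 61 in libraries labelled IRF8KO from P14 to adults. Genes higher at all 3 ages ran from 116 to 245 and genes lower at all 3 ages from 93 to 227. Among adult lists whose direction reversed, adjusted p ran from 0.109 to 0.876 (cell cycle), 0.00312 to 0.745 (disease-associated), 0.376 to 0.876 (erythroid), 0.0971 to 0.471 (neuron), 0.231 to 0.876 (phagocytic) and 0.0225 to 0.928 (cholesterol). At P14 it ran from 0.674 to 0.931 (disease-associated), 0.501 to 0.888 (inflammatory) and 0.228 to 0.876 (mitochondrial).

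Single genes whose fold change reversed when 1 library was left out were all ones that had not passed. In adults the log2 fold change of Trem2 ran from -1.13 to 0.13, that of Cd74 from -0.396 to 0.266 and that of P2ry12 from -2.59 to 0.324, and the P14 minus P9 difference of Pf4 from -0.358 to 0.619. P2ry12 at P9 passed with DESeq2 (-2.27, adjusted p = 0.00848) with RLE factors (-2.26, adjusted p = 0.0426) and without library 3 of IRF8KO P9 (-2.99, adjusted p = 0.0323), and Mrc1 at P9 passed with DESeq2 (2.04, adjusted p = 0.0271). Far more calls were lost than gained, 111 without 1 library and 3 with RLE factors, while 1891 single-gene results stayed the same and 8 reversed. The lost calls were mostly fits without 1 library, of Mthfsd, Tap1, Psme1, Ciita, Lss, Tmem119 and P2ry12 at P14, of C3ar1, Abcg1 and Ifit3 at P9, and in adults of Mrc1, Irf4, Jun, Nr4a1, Bub1b, Tnf, Cxcl2, Tlr2, Plin2, Il6, Cd300lf, Siglech, Fcrls, Oasl2, Oas2 and Ifit3. Between ages they were of Tgfb1, Dab2, Mcm2, Cdk1, Cd74 and Mbp in genotype effects, of Lpl, Fabp5, Selplg, Sparc and H2-Ab1 in WT and of Jag1, H2-Eb1, Cfp, Cbr2, Ms4a4a, Fos and Nr4a1 in libraries labelled IRF8KO. With RLE factors Psme1 at P14 (adjusted p = 0.0536), Plin2 in adults (0.0543) and Dab2 for adult minus P14 (0.0558) were lost.

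Replicate numbers gave no sign of pairing at P9 and P14, where libraries of the same number were not more alike across genotypes than others (r = -0.0266, 0.243 and -0.0341 at P9, -0.369, 0.146 and -0.257 at P14). In adults same-number pairs had r = 0.304 against -0.304 for the others, which with 2 libraries per group differ in sign by construction, so pairing there stays open. With a replicate block 2174 genes were called at P9, 5280 at P14, 456 in adults, 2283 for the averaged effect, 3487 for P14 minus P9, 686 for adult minus P14, 775 and 4320 from P9 to P14 in WT and in libraries labelled IRF8KO, and 5282 and 46 from P14 to adults. Lists called were 11, 12 and 13. The phagocytic list in adults reversed (adjusted p = 0.954), as did adult Cd74 (log2 fold change 0.0344). With this block P2ry12 at P9 passed (adjusted p = 0.0449), while Ciita at P14 (0.0843), Cd300lf, Jun, Cxcl1, Cxcl2 and Il6 in adults (0.0919, 0.0996, 0.0579, 0.0716 and 0.0667) and Dab2 and Cdk1 for adult minus P14 (0.0619 and 0.0597) were lost.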

Other observations

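The tests of antigen presentation, technical and remaining cell type lists were set before the data were examined, and the relation of the neuron list to reads outside genes was chosen only after results were seen.

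Several genes of antigen presentation were lower in libraries labelled IRF8KO, although most members of these lists were not called. H2-DMa, the peptide exchanger of MHC class II, fell by 3.08 at P9, 4.31 at P14 and 4.75 in adults (adjusted p = 0.000195, 8.16e-06 and 0.000104, edgeR quasi-likelihood), although exons shared with another gene make it uncertain. Cd74, the invariant chain, fell by 2.24 and 2.53 at P9 and P14 but was at 101.9 against 103.3 CPM in adults. Ciita, the master regulator of the class, rose by 3.22 at P14. The MHC class II list had 0 higher and 3 lower of 10 at P9 (3 lower when adjusted over the list alone), 1 and 4 at P14 (1 and 7) and 0 and 3 in adults (0 and 4). Its medians were -0.85, -1.06 and -1.02, with camera adjusted p = 0.0377, 0.000532 and 7.91e-06, and adjusted p = 0.591, 0.368 and 0.246 with an estimated correlation. MHC class I genes had 0 higher and 1 lower of 15 at P9 (1 when adjusted over the list alone), 0 and 4 at P14 (0 and 1) and 0 and 0 in adults (0 and 0), with medians 0.24 (mean -0.22, upward rank), -0.58 and -0.37 (camera adjusted p = 0.446, 0.00354 and 0.0137, and with an estimated correlation adjusted p = 0.368 at P14 and 0.45 in adults). Class II lost its P9 call without library 2 or 3 of WT P9 or library 3 of IRF8KO P9 (camera adjusted p = 0.0549, 0.0855 and 0.0976), and class I its adult call without library 2 of WT or library 1 of IRF8KO (0.475 and 0.554) and with fry (0.285). Tap1, the peptide transporter, and Psme1, a proteasome activator, both fell by 0.96 at P14. These calls hung on single libraries: without 1 library Tap1, Psme1 and Ciita did not pass in 4, 4 and 3 of 6 fits (adjusted p = 0.0611 to 0.0963, 0.071 to 0.147 and 0.0539 to 0.0923).

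Immediate early genes, which dissociation can induce, were higher at P9 (7 higher and 0 lower of 19, the same when adjusted over the list alone, median 0.66, camera adjusted p = 0.000852, and adjusted p = 0.366 with an estimated correlation). In adults 4 were higher and 0 lower (10 when adjusted over the list alone, median 1.54, camera adjusted p = 1.92e-06, and adjusted p = 0.218 with an estimated correlation), and at P14 4 and 4 (5 and 4, median 0.33 and mean 0.40 against a downward rank, camera adjusted p = 0.527). Egr1 rose by 2.71 and Rgs1, a brake on chemokine receptors, by 5.47 at P9, and Jun by 2.53 and Nr4a1 by 2.93 in adults. Jun lost its call in 2 of 4 fits without 1 library (adjusted p = 0.264 and 0.566) and Nr4a1 in 3 (0.0583 to 0.387). Mitochondrially encoded genes, 8 tested, had 1 higher at each age (1 when adjusted over the list alone), mt-Nd3. Their medians were 0.08, 0.32 and 0.83 (camera adjusted p = 0.107, 0.553 and 0.000852, and adjusted p = 0.368 with an estimated correlation in adults), and the adult call was lost without library 2 of WT (camera adjusted p = 0.505) and with fry (0.0985). At P9 the list passed without library 1 of WT or library 2 of IRF8KO (0.0355 and 0.038).

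Of the peripheral immune lists those of monocytes and neutrophils passed at P9 and in adults, with the preset correlation only. The monocyte list, 9 tested, had 3 higher and 1 lower at P9 (4 and 2 when adjusted over the list alone), 3 and 1 at P14 (4 and 1) and 2 and 0 in adults (3 and 0). Its medians were 1.11, 2.36 and 2.05, or 1.72 and 1.76 at P14 and in adults with zero-read genes at their bound (camera adjusted p = 0.0461, 0.416 and 0.0461, and adjusted p = 0.246 with an estimated correlation at P9 and in adults). Its call was lost at P9 without library 2 or 3 of WT P9 (camera adjusted p = 0.113 and 0.0521), and in adults without any 1 of the 4 libraries (0.0567 to 0.132). Itga4, the integrin alpha 4 chain, rose by 6.07, 8.41 and 5.49, while Plac8 fell by 3.84 at P9. The neutrophil list, 6 tested, had 1, 2 and 1 higher (4, 2 and 3 when adjusted over the list alone), with medians 1.47, 2.25 and 3.89, or 2.2 and 2.5 at P14 and in adults at the bound (camera adjusted p = 0.00318, 0.32 and 0.00858, and adjusted p = 0.0685 and 0.0909 with an estimated correlation at P9 and in adults). The adult neutrophil call was lost without library 1 of either genotype (camera adjusted p = 0.0964 for WT and 0.0521 for IRF8KO). The dendritic cell list, 7 tested, had 0 higher and 1 lower, 2 and 2, and 1 and 0, the same when adjusted over the list alone (medians 0.15, 0.00 and 0.10, camera adjusted p = 0.491, 0.746 and 0.485). Its mean of 0.07 at P14 opposed a downward rank, and its mean in adults was -0.58 with an upward rank. The lymphocyte list, 6 tested, had 2 and 2, 2 and 2, and 0 and 2, the same when adjusted over the list alone (medians 0.38, 0.81 and 0.47, camera adjusted p = 0.746, 0.45 and 0.0811, the last 0.0307 without library 1 of WT), with downward ranks against positive means at P14 (0.74) and in adults (0.08). Ighm, the immunoglobulin mu chain, fell by 7.99, 8.18 and 3.11 from 552.3, 598.0 and 467.7 CPM in WT.

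At P14 the astrocyte and oligodendrocyte lists were higher, and the vascular and erythroid lists did not pass. The astrocyte list, 9 tested, had 0 higher and 1 lower at P9 (0 and 1 when adjusted over the list alone, median -0.75, camera adjusted p = 0.14, but 0.038 without library 2 of IRF8KO P9), 7 and 1 at P14 (7 and 1 when adjusted over the list alone, median 1.81, camera adjusted p = 0.0398, and adjusted p = 0.368 with an estimated correlation) and 0 and 1 in adults (0 and 1 when adjusted over the list alone, median 0.32, mean -0.09, downward rank, camera adjusted p = 0.527). The astrocyte call at P14 was lost without library 2 of WT P14 or library 3 of IRF8KO P14 (camera adjusted p = 0.0599 and 0.0663). Slc1a2, the glutamate transporter, rose by 3.40 and Aldoc by 2.67 at P14. The oligodendrocyte list, 12 tested, had 1 and 1 at P9 (1 and 1 when adjusted over the list alone, median -0.12 and mean -0.05 against an upward rank, camera adjusted p = 0.579), 7 and 1 at P14 (9 and 1 when adjusted over the list alone, median 2.41, camera adjusted p = 0.0474, and adjusted p = 0.53 with an estimated correlation) and 1 and 1 in adults (1 and 1 when adjusted over the list alone, median -0.52, camera adjusted p = 0.215). The oligodendrocyte call at P14 was lost without library 2 or 3 of WT P14 or library 3 of IRF8KO P14 (camera adjusted p = 0.0793, 0.0771 and 0.164), and with RLE factors (0.051). Mbp rose by 2.45 at P14, and Cspg4, a proteoglycan that macrophages can also express, by 5.46, 7.51 and 3.84 at the 3 ages. Endothelial and mural genes, 10 tested, had 0 and 3 at P9 (0 and 3 when adjusted over the list alone, median -2.67, camera adjusted p = 0.0111, and adjusted p = 0.178 with an estimated correlation), 2 and 3 at P14 (2 and 3 when adjusted over the list alone, median -0.09, camera adjusted p = 0.214) and 0 and 0 in adults (0 and 0 when adjusted over the list alone, median -1.47, camera adjusted p = 0.0253, and adjusted p = 0.218 with an estimated correlation). The adult vascular call was lost without library 1 of WT or library 2 of IRF8KO (camera adjusted p = 0.523 and 0.153), and with fry (0.0931). Erythroid genes, 7 tested, had 0, 1 and 0 higher and 0 lower, the same when adjusted over the list alone (medians -0.81, 1.43 and 0.41, camera adjusted p = 0.0824, 0.214 and 0.777, the first 0.00203 without library 1 of IRF8KO P9).

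The level of the neuron list and the share of reads outside genes both differed between groups. The list stood at 2.80 ± 0.27 log2 CPM (SD) in WT P9, -0.12 ± 0.34 in IRF8KO P9, 0.63 ± 0.41 in WT P14, 4.21 ± 0.96 in IRF8KO P14, 4.70 ± 0.80 in WT adults and 4.75 ± 0.31 in IRF8KO adults. Over all 16 libraries the 2 correlated (r = 0.806), a value that holds the differences between groups. Within groups, where few libraries remain to judge by, no relation was detected (r = -0.172, permutation p = 0.612, Spearman rho = -0.129, permutation p = 0.743, over 100000 permutations, and r = -0.403 without the 2 most distant libraries). A relation within groups is thus neither shown nor excluded.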
